A study of Mus musculus with 4 samples.

How the data were processed

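RNA from CD4 T cells of mouse lymph nodes was measured on a single-colour Agilent microarray, with 4 arrays in all. Per the labels, the cells came from male wildtype mice or from mice with a knockout of Med23, a subunit of the Mediator complex, with or without stimulation, which lasted 6 h. The series design names the T cell receptor as its target, and how the CD4 T cells were selected is not given in the sources used here. Each of the 4 combinations had 1 array, so 1 sample stood for each group. No group had replicates, and the number of arrays limits the precision of every value. Per the labels' protocols, 1 µg of total RNA per sample was amplified and labelled with Cy3.

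The deposited raw table holds the intensity of each spot on a linear scale, as left by all steps of Agilent Feature Extraction 10.7.3.1 within an array, per the file headers and the submitters' processing notes. It is not normalized between arrays and carries no detection or saturation flags. It lists 44397 spots, of which 1377 are controls, and 39429 probes, of which 399 have 10 spots each. A second deposited table holds log2 values that the authors normalized between arrays with GeneSpring GX 11.5.1, per the file headers, for 17878 of the probes. The method and the filter behind that table are not given in the sources used here. Its values differed from a quantile normalization of the log2 raw signals by an SD of 0.0237, with a lowest correlation of 0.99995 over the arrays, so scale, direction and array order were settled from the data. The medians of its columns were log2 8.54 and 8.51 for the unstimulated and stimulated wildtype arrays and 8.53 and 8.54 for the arrays labelled knockout. The genome build behind the array annotation is not given in the sources used here, and no coordinates are printed.

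The main values start from the raw intensity. Spots of a probe were averaged on the log2 scale, and the 75th percentile over non-control probes was subtracted in each array. Values below a floor, the median over the arrays of their 40th percentiles (log2 -5.01), were set to the floor. Probes were named by matching the accession on the array, without version, to a RefSeq gene table of assembly GRCm38.p6, used for names only. Of the probes, 26299 were named, giving 19896 genes, and 13130 stayed unnamed and were left out of gene values. A gene's probes were averaged: 14557 genes had 1 probe and 5339 had several. Genes whose probes differ in direction were not named among the largest differences. A gene counts as measured in a comparison when it lies above the floor in at least 1 array compared. Where 1 side is at the floor, the difference is a bound, written as "at least" or, for a negative one, "at most". A list's median takes such genes at the floor and is no bound, and a gene with some of its probes at the floor is printed without these words.

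Signal strength differed between arrays. The 75th percentile of the raw signal was 269.1 in the unstimulated wildtype array, 680.8 in the stimulated wildtype array, and 332.6 and 243.7 in the unstimulated and stimulated arrays labelled knockout. The stimulated wildtype array was thus 2.05 to 2.79 times as bright as the others. Above the floor lay 59.8%, 62.7%, 59.5% and 60.2% of the probes, in the same order. Negative control spots had median signals of 2.96, 3.93, 4.02 and 3.36, under the floor signals of 8.35, 21.1, 10.3 and 7.57. No arrays held identical values. In the 399 probes with 10 spots, the SD of a log2 difference between a pair of arrays was 0.091 to 0.135 for probes brighter than log2 1. It was 0.514 to 0.83 for those between the floor and log2 -3. These SDs cover noise between spots and not the spread between animals or cultures.

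There were 5 comparisons: stimulated against unstimulated in wildtype and in the arrays labelled knockout, labelled knockout against wildtype without and with stimulation, and the stimulation difference in the arrays labelled knockout minus that in wildtype. With 1 array per group no test was possible within a comparison and no p-value is given. A test of stimulation pooled over the genotypes was not run. Genes are called higher or lower by size alone, at a 2-fold difference. Gene lists are described by the median log2 difference of their measured members, set among 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its percentile is under 1 or over 99, as a description of these arrays. The 24 lists, with 609 genes of which 590 were on the array, were written before the data were examined, as were the comparisons, the named-genes rule and all alternatives not said to be added later. They cover early T cell receptor response, cytokines, naive and quiescence genes, negative regulators, MAPK feedback, targets of serum response factor, Mediator, cell cycle, glycolysis and nutrient uptake, ribosome biogenesis, interferon response, helper lineage, effector and memory, regulatory T cells, cholesterol and lipid synthesis, apoptosis, heat shock and stress, and T cell identity. Markers of CD8 T cells, B cells, myeloid and dendritic cells, natural killer cells, red cells and stroma were included for cells that a CD4 preparation could hold. A gene may stand in more than 1 list: 12 of the 33 early response genes and 10 of the 31 serum response factor targets are also in another list. So are 7 of the 39 negative regulators and 6 of the 20 regulatory T cell genes. The same holds for 3 of the 17 natural killer and 1 of the 30 myeloid and dendritic markers. Of the 30 myeloid and dendritic markers 20 lay above the floor in the unstimulated wildtype array, as did 16 of 24 B cell and 4 of 14 red cell markers. A further 6 lists were drawn up after the data had been seen: neutrophil granule proteins, mature dendritic cell genes, plasma cell genes, aminoacyl-tRNA synthetases, proteasome subunits and the GIMAP family.

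The named genes were chosen by a fixed rule. In each comparison it takes the 8 genes with the largest difference per direction among genes with every probe above the floor in every array compared, whose brighter array is at or above the 60th percentile and whose probes differ in 1 direction, passing over predicted genes. It also takes the 4 members of each list with the largest difference, 8 single genes (Med23, Klf2, Cdkn1b, Egr2, Il2, Ifng, Il2ra and Cd69), and up to 10 genes per direction that differ 2-fold both without and with stimulation. Genes named outside it are said to be so. Some genes that the rule takes are not reported here.

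The steps were tested on simulated data for the comparison of stimulated with unstimulated wildtype, run on 19896 genes with 200 genes changed 3-fold and 1 array 2.5 times as bright. The changed genes were drawn from genes with scaled values above -1 in the unstimulated wildtype array. Every simulated array was a copy of that array with spot noise. Dim changed genes and the spread between samples were therefore not tested. Of the changed genes 99.0% were recovered, with a median log2 size of 1.59. Of 7036 unchanged bright genes 0 were called, and of 13752 unchanged measured genes 100 were called. All 20 changed lists passed the 99th percentile, and 1 of 200 unchanged lists passed either limit. Every member of a changed list was raised 3-fold and unchanged lists were random draws, so this outcome was largely fixed in advance. Lists of mixed or co-regulated genes were not tested.

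The alternatives were quantile normalization, scaling to the median, cyclic loess (limma 3.58.1 in R 4.3.3, 3 iterations), the authors' normalized values, floors at the 20th and 60th percentiles, no floor with a pseudocount at the 10th percentile of the scaled signal, the brightest probe of each gene, and thresholds of 1.5-fold and 3-fold. Counts without marker genes of other cell types, and counts of genes above the floor in all 4 arrays, were added after the data had been seen. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.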

Results

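Gene expression was profiled in CD4 T cells, the helper lymphocytes of the adaptive immune system, from lymph nodes of wildtype mice and of mice labelled as Med23 knockout. Med23 is a subunit of Mediator, the complex that links transcription factors to RNA polymerase II. Cells were either unstimulated or stimulated for 6 h through the T cell receptor (TCR), and the series asks which part of the TCR response depends on Med23. Each of the 4 groups had 1 array and no replicates, so differences are reported by size and have no replicate check. Between spots of the same probe, at most 0.17% of pairs differed 2-fold on a pair of arrays at levels above 1, against at least 6.79% between the floor and -3, so calls of dim genes are the less certain ones. Levels are log2 signal relative to the 75th percentile of the array. Unless another quantity is named, values in parentheses are log2 differences.

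The targeted gene was read first. The single Med23 probe had a level of -1.59 in the unstimulated wildtype array and -0.75 in the stimulated wildtype array, against -1.66 and -2.29 in the unstimulated and stimulated arrays labelled knockout. Med23 was thus 2.91-fold lower in the array labelled knockout after stimulation (-1.54) and differed by -0.07 without stimulation. The unstimulated pair of arrays therefore goes against the label. Where the probe lies relative to the deleted exons is not known, so it may check nothing. The knockout arrays are called "labelled knockout" for this reason, and every direction between genotypes rests on the labels. Of the 31 Mediator genes measured in the unstimulated arrays 0 were 2-fold different (median 0.02). Of the 32 measured in the stimulated arrays 2 were 2-fold lower and 0 higher (median 0.28), Med23 and Med31 (-1.35). A lower value in that pair was thus not particular to Med23.

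The wildtype comparison asks how normal cells respond to 6 h of TCR stimulation. Early response factors, cytokines and ribosome assembly genes were higher, and genes of resting naive T cells were lower. Of 32 measured early TCR response genes 25 were 2-fold higher and 0 lower (median 2.09), led by the nuclear receptors Nr4a2 (7.43) and Nr4a1 (4.14) and by Irf4 (4.47), a transcription factor that scales with TCR signal strength. Of 32 cytokine and chemokine genes 26 were higher and 1 lower (median 2.48, and 1.29 with the floor at the 60th percentile). Ccl4 was 79.9-fold higher (6.32), and Xcl1 (6.09), Il17a (6.00), Il2 (4.05) and Ifng (2.47) were also higher. Ccl5 was the 1 lower member (-2.46). Of 32 ribosome biogenesis genes 28 were higher and 0 lower (median 1.60), with Odc1, the rate-limiting enzyme of polyamine synthesis, at 3.89 and nucleolin (Ncl) 6.96-fold higher. The naive and quiescence list went the other way, with 15 of 32 genes lower and 0 higher (median -0.99), among them Dapl1 (-3.28), Txnip (-3.06) and Foxo1 (-2.21). Klf2, which keeps naive T cells quiescent, differed by -0.98 and the cell cycle inhibitor Cdkn1b by -0.54, neither past the 2-fold rule, though Klf2 was past it in 3 of the 8 alternatives.

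Smaller groups moved with the wildtype response. Heat shock and stress genes were higher in 14 of 27 cases and lower in 1 (median 1.03), with Chac1 at 3.71 and Hsp90aa1 at 3.35, while Ddit4, an inhibitor of mTORC1, was the lower member (-4.83). Of 19 regulatory T cell genes 10 were higher (median 1.08), including the interleukin-2 receptor chain Il2ra (2.44) and Lrrc32 (1.89). Glycolysis and nutrient uptake genes were higher in 9 of 24 and lower in 2 (median 0.47), with hexokinase Hk2 at 4.98 and Pdk1 at -1.83. Cholesterol and lipid genes split into 10 higher and 5 lower of 28 (median 0.51), the lower side including the sterol exporters Abca1 (-2.84) and Abcg1 (-2.56). MAPK feedback genes (median 0.63, 7 of 17 higher, 2 lower), led by Spry1 (5.92), targets of serum response factor (median 0.65, 12 of 30 higher, 2 lower), led by Egr4 (at least 4.84), and apoptosis genes (median 0.43, 9 of 22 higher, 2 lower), led by Bcl2a1d (2.54), also stood above the matched lists. The apoptosis list kept this place in 4 of the 8 alternatives, and the MAPK feedback and cholesterol lists each lost it under 1 other floor. Negative regulators had 14 of 39 genes higher and 9 lower (median 0.22), including Pdcd1 (2.74), Egr2 (3.29) and Sit1 (-3.93), and did not stand apart. Neither did Mediator (0.31), cell cycle (-0.04), interferon response (0.25), helper lineage (0.09), effector and memory (-0.30), T cell identity (-0.28), CD8 (-1.39), natural killer (-0.25) or stroma (-0.13) genes. The activation marker Cd69 was higher (1.69), as was Tbx21 (2.99), the transcription factor of type 1 helper cells.

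Many large positive differences in this comparison belonged to genes of other blood cells. Of 10 measured red cell genes 9 were higher and 0 lower. Their median was 3.94, with genes at the floor taken at the floor. It was 1.69 in the authors' values, 2.37 with the floor at the 60th percentile and 2.70 with the pseudocount. Alpha globin Hba-a2 was 1243-fold higher (10.28). Of 25 myeloid and dendritic genes 18 were higher and 2 lower (median 1.65, and 2.78 with the brightest probe). Lysozyme Lyz2 (at least 7.71), S100a9 (at least 7.70) and S100a8 (at least 6.66) were at the floor in the unstimulated wildtype array. The neutrophil genes Ctsg (8.87), Stfa2 (8.72), Chil3 (8.50), Ifitm6 (8.45), Lrg1 (6.59) and Lcn2 (6.34) were 6 of the 8 genes that the naming rule takes on the higher side, beside Hba-a2 and Sema7a (7.39). The rule passes over genes with a probe under the floor, such as Nr4a2. All 25 measured genes of the granule protein list, drawn up after the data had been seen, were 2-fold higher (median 6.34). In the stimulated wildtype array 24 of these 25 genes, 9 of the 10 red cell genes and 13 of the 25 myeloid and dendritic genes were at least 2-fold higher than in each other array, as the plot of marker genes shows, and they accompany every difference that uses this array. Anxa1 (3.95), counted among the effector and memory genes, is also abundant in neutrophils. B cell genes were lower in 7 of 19 and higher in 2 (median -0.77), a place lost with the floor at the 60th percentile.

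**Figure D1:**
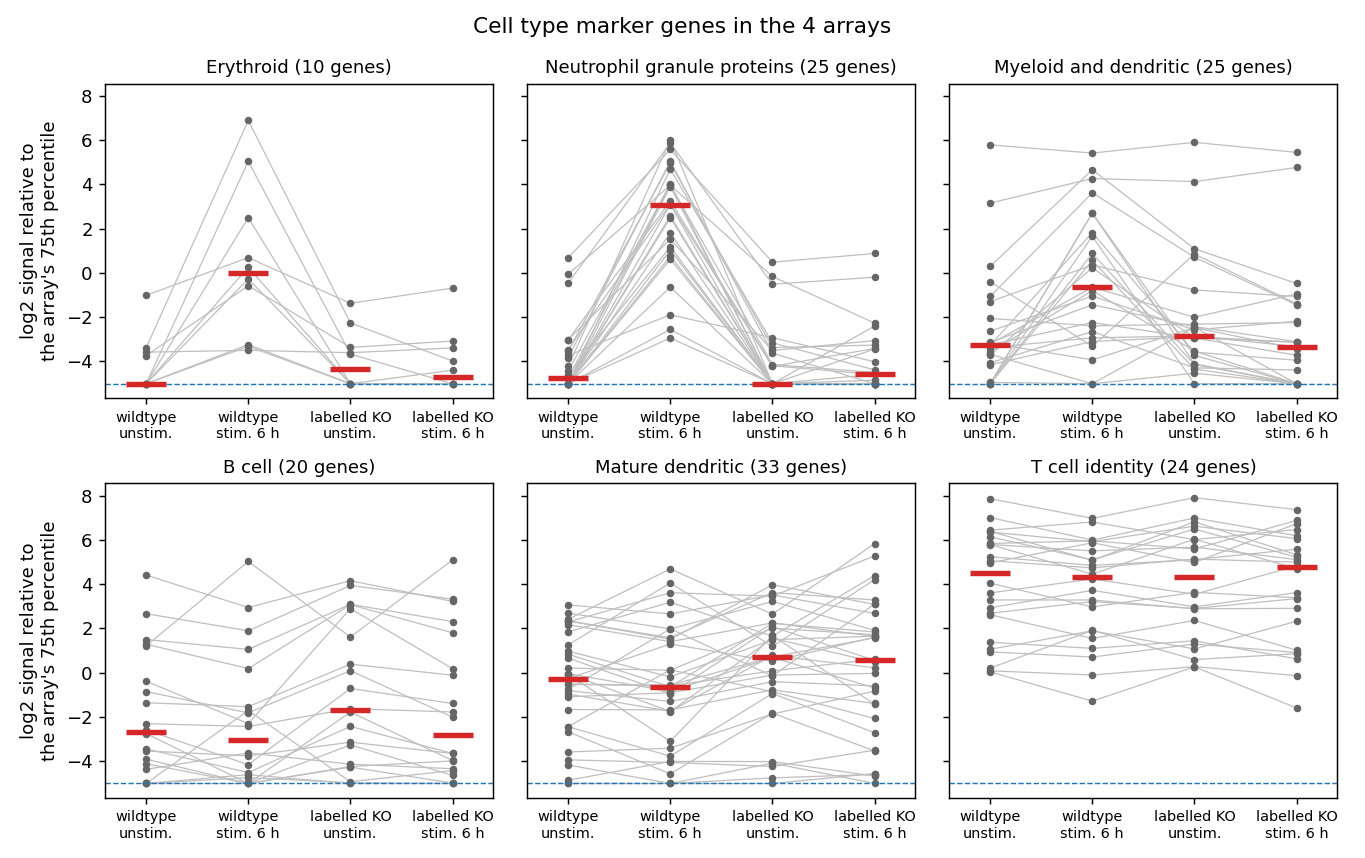
Levels of marker genes in the 4 arrays (y axis, log2 signal relative to the 75th percentile of the array; x axis, the arrays). Each dot is a gene, grey lines join a gene's values, red bars are medians over genes and the dashed line is the floor at -5.01; the medians of red cell genes and of myeloid and dendritic genes peak in the stimulated wildtype array (-0.01 and -0.65).

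Over all genes, 2079 of 14619 measured genes were 2-fold higher after stimulation in wildtype and 1870 were lower. Higher genes made up 52.6% of the called genes, against 36.2% with scaling to the median and 41.6% with the authors' normalized values. The median of all genes was -0.02, and -0.23 and -0.18 under these alternatives, so sizes are best read against the matched random lists, whose medians lay between -0.13 and 0.15. By the naming rule the largest lower values were those of Rwdd2a (-9.90), Dtx1 (-6.09), Apol9b (-5.68), Vmn2r85 (-5.48), Ddit4 (-4.83), Lrrc75b (-4.56), Igfbp4 (-4.35) and Ggt5 (-4.09). Rwdd2a and Vmn2r85 have 1 probe each and were bright in the unstimulated wildtype array alone, at levels of 4.99 and 3.63.

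The same comparison in the arrays labelled knockout asks whether stimulation acts alike when Med23 is targeted, and uses neither wildtype array. Early response, cytokine and ribosome genes were again higher and naive genes lower. Of 33 early response genes 26 were 2-fold higher and 0 lower (median 2.60), with Nr4a2 at 8.34, Nr4a1 at 4.93 and Nr4a3 at least 4.54. Of 32 cytokines 26 were higher and 2 lower (median 2.84, and 2.21 with the floor at the 60th percentile). Ccl4 was 351-fold higher (8.45), followed by Xcl1 (6.72), Il17a (6.20), Ccl3 (at least 6.00), Ifng (5.23) and Il2 (4.97). Of 32 ribosome biogenesis genes 31 were higher (median 2.15), with the spermidine synthase Srm at 3.29. Of 32 naive and quiescence genes 19 were lower and 2 higher (median -1.30). Dapl1 (-4.21) and Il6ra (-3.001) led them, and Klf2 (-1.62) and Cdkn1b (-1.64) were past the 2-fold rule.

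Metabolic and stress genes were also higher in the arrays labelled knockout after stimulation. Cholesterol and lipid genes were higher in 16 of 29 and lower in 4 (median 1.21), with the sterol demethylase Cyp51 at 3.27 and the isomerase Idi1 at 2.89, against Abcg1 at -3.04. Glycolysis and uptake genes were higher in 13 of 24 and lower in 2 (median 1.06), with Hk2 (3.99) and the amino acid carriers Slc1a5 (2.43) and Slc3a2 (2.36). Heat shock and stress genes were higher in 19 of 27 and lower in 1 (median 1.42), led by Atf3 (6.78) and Chac1 (4.48). Negative regulators (16 of 39 higher, 8 lower, median 0.65), with Pdcd1 (3.04) and Egr2 (4.06), MAPK feedback genes (8 of 18 higher, 1 lower, median 0.87) and regulatory T cell genes (10 of 19 higher, 1 lower, median 1.00), with Il2ra (2.63), stood above the matched lists. The negative regulators did not do so in the authors' values. Effector and memory genes stood below, with 10 of 27 lower and 2 higher (median -0.73). S100a4 (-3.09) and Ccr2 (at most -3.44) were lower and Gzmb (4.69), the granzyme of cytotoxic cells, was higher. Targets of serum response factor had 11 of 30 genes higher and 3 lower (median 0.50) and did not stand apart, but did in 6 of the 8 alternatives. Apoptosis (0.47), Mediator (0.33), helper lineage (0.24), interferon response (0.08), cell cycle (-0.26), CD8 (-0.55), natural killer (-0.55) and red cell (0.25) genes did not stand apart, but the natural killer list did in 1 alternative. Among their members Tbx21 was higher (4.62), as were the interferon-inducible Cxcl10 (4.28) and the activation marker Cd69 (2.63).

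The B cell, myeloid and dendritic, stroma and T cell identity lists stood below the matched lists after stimulation in the arrays labelled knockout, each with a minority of genes past the rule. B cell genes were lower in 6 of 19 and higher in 1 (median -0.68), with Jchain, the joining chain of immunoglobulins, at -2.71. Myeloid and dendritic genes were lower in 6 of 24 and higher in 1 (median -0.57), stroma genes were lower in 6 of 14 (median -0.74), and T cell identity genes were lower in 5 of 24 and higher in 4 (median -0.32). The myeloid, stroma and T cell identity lists stood below in 6, 5 and 5 of the 8 alternatives. In all, 1919 of 14229 measured genes were higher and 1963 lower, and higher genes made up 49.4%. Among the largest differences were Bdh2 (7.19), Crabp2 (6.74) and Sult2b1 (6.65) on the higher side. Dtx1 (-5.64), Lrrc75b (-5.06), Apol9b (-5.02), Drc1 (-5.01), Cmtm8 (-4.99), Dmbt1 (-4.98), Igfbp4 (-4.92) and Eya2 (-4.62) were on the lower side.

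**Figure D2:**
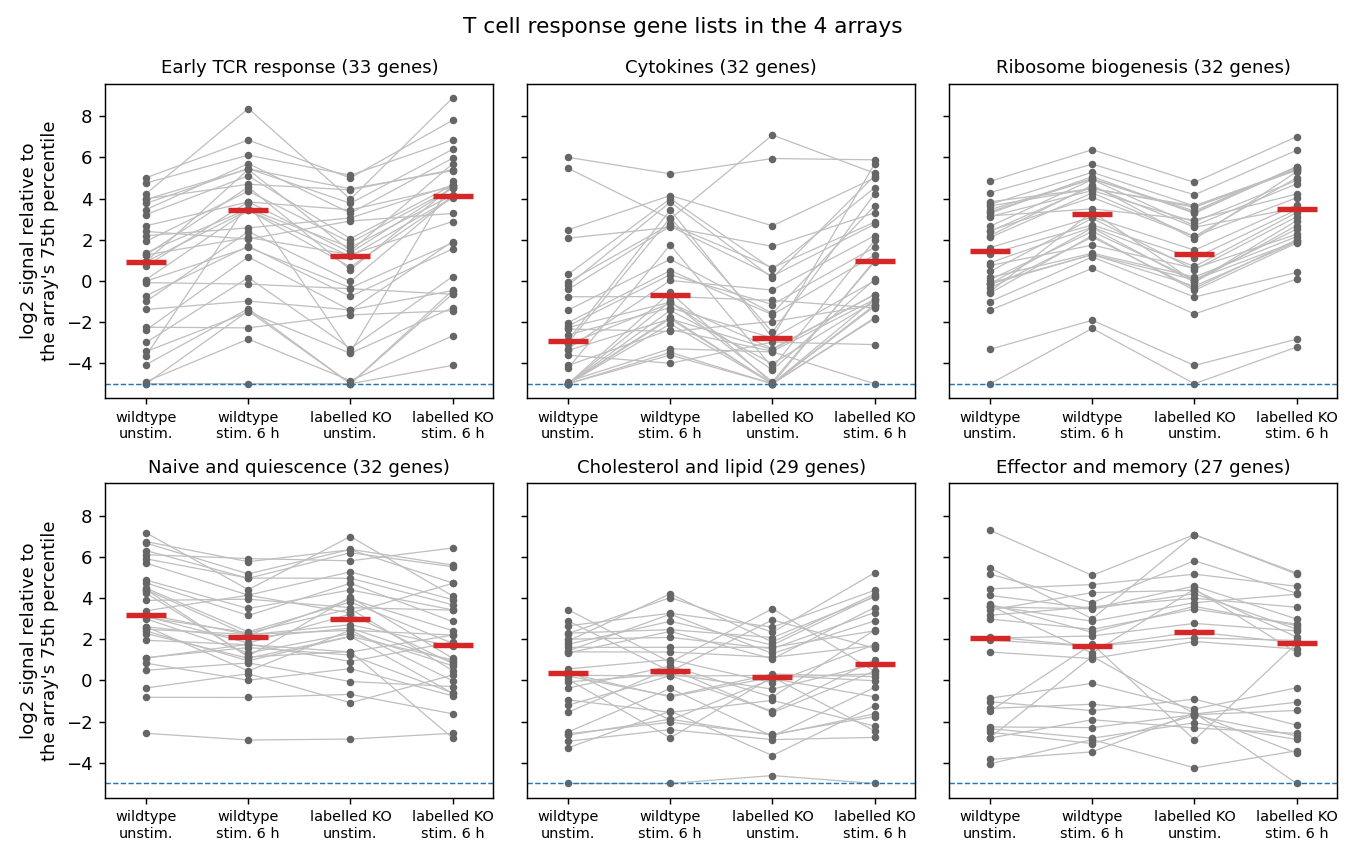
Levels of 6 gene lists of the T cell response in the 4 arrays (y axis, log2 signal relative to the 75th percentile of the array; x axis, the arrays). Each dot is a gene, grey lines join a gene's values, red bars are medians over genes and the dashed line is the floor; the cytokine median goes from -2.95 to -0.67 in wildtype and from -2.78 to 0.95 in the arrays labelled knockout.

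The stimulation differences of the genotypes, which share no array, ran together across genes. Over 12217 genes above the floor in all arrays, Pearson's r was 0.665 and Spearman's rho 0.635, across genes that are not independent replicates, and r was 0.552 with the floor at the 20th percentile and 0.514 with a pseudocount. Of 3214 genes 2-fold different in wildtype, 2838 (88.3%) had the same sign in the arrays labelled knockout. Of 1555 genes higher in wildtype 855 were 2-fold higher in both, and of 1659 lower in wildtype 963 were lower in both. A 2-fold difference in opposite directions was found for 61 genes higher in wildtype and for 8 lower in wildtype.

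**Figure D3:**
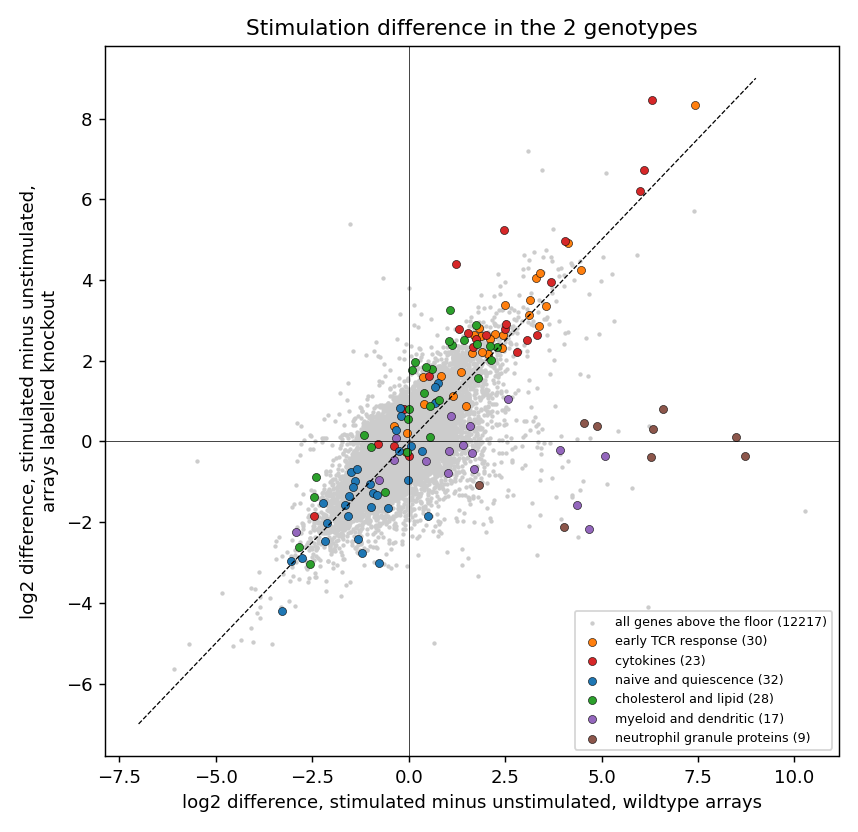
Log2 difference between stimulated and unstimulated cells in the wildtype arrays (x axis) against that in the arrays labelled knockout (y axis), 1 dot per gene above the floor in all arrays; colours mark gene lists and the dashed line marks equal differences. Cytokines such as Ifng (2.47 and 5.23) lie above the line, and granule protein genes such as Lcn2 (6.34 and 0.32) lie far to the right of it.

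The difference of these differences addresses dependence on Med23 most directly. The cholesterol and cytokine lists stood above the matched lists, toward a more positive stimulation difference in the arrays labelled knockout. In each list a minority of genes was past the rule. Of 29 cholesterol and lipid genes 12 had a stimulation difference at least 2-fold larger, that is more positive, and 0 smaller (median 0.80, matched lists 0.18). They included Cyp51 (2.20), Msmo1 (1.81), Sc5d (1.67) and Dhcr7 (1.53), enzymes of sterol synthesis. A larger value can be a smaller fall, as for Dhcr7. Its level went from 0.485 to -1.927 in wildtype and from 0.087 to -0.794 in the arrays labelled knockout. Of 32 cytokines 11 had a stimulation difference at least 2-fold larger and 1 at least 2-fold smaller (median 0.67, matched lists 0.10). Ccl1 (3.17), Ifng (2.77) and Il6 (2.37) led them, with both unstimulated arrays at the floor for Il6, and Il24 went the other way (at most -3.14). Ccl1 already differed by -2.06 between the unstimulated arrays, with a level near the floor (-4.34) in the one labelled knockout. The cytokine list did not stand apart in the authors' values. Naive and quiescence genes (5 of 32 smaller, 1 larger, median -0.02, matched lists 0.29) and T cell identity genes (1 of 24 smaller, 1 larger, median -0.04, matched lists 0.32) stood below. Klf7 was at -2.33, and the identity genes past the rule were Fyn at -1.44 and Ptprc at 1.17 on opposite sides. With scaling to the median their medians were 0.27 and 0.25, above 0. Neither list kept its place in all alternatives, the naive list losing it in the authors' values and the identity list under quantile normalization. Cdkn1b (-1.10) was past the rule, and stayed so in 7 of the 8 alternatives. Klf2 (-0.64), Egr2 (0.76), Il2 (0.92), Cd69 (0.93) and Il2ra (0.20) were not past it, though Egr2, Il2 and Cd69 were in 1 alternative.

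Of the 24 lists, those of red cells and of myeloid and dendritic cells had the lowest medians. Red cell genes (9 of 10 lower, 0 higher, median -3.80, and -0.97 to -2.90 in 4 alternatives) and myeloid and dendritic genes (18 of 25 lower, 0 higher, median -1.78, -1.07 in the authors' values and -2.63 with the brightest probe) stood below the matched lists, as did effector and memory genes (5 of 27 lower, 2 higher, median -0.34) with Anxa1 (-5.87), S100a6 (-3.12) and S100a10 (-1.64). The red cell list lost its place in the authors' values. By the naming rule the largest negative values, those of Hba-a2 (-12.00), Plbd1 (-10.29), Stfa2 (-9.08), Chil3 (-8.39), Alox5ap (-6.93), Tyrobp (-6.84), Tgfbi (-6.74) and Stfa3 (-6.67), were globin and myeloid genes high in the stimulated wildtype array. On the positive side the rule takes Sbk1 (6.92), Vmn2r85 (4.99), Olfr213 (4.71), Bdh2 (4.10), Pramel20 (3.37), Gtpbp3 (3.34), Ltk (3.32) and Crabp2 (3.28). Of these, Vmn2r85 was bright in the unstimulated wildtype array alone, at a level of 3.63. Bdh2 had levels of 2.16 and 2.66 in the stimulated wildtype and labelled knockout arrays, but -0.93 and -4.54 in the unstimulated ones. Olfr213 and Ltk have 1 probe each, with levels of -0.949 and -0.945 in the stimulated array labelled knockout and -3.29 or lower elsewhere. In all, 1076 of 15230 genes had a stimulation difference at least 2-fold larger in the arrays labelled knockout and 1620 at least 2-fold smaller, so 39.9% were on the larger side, against 66.9% with scaling to the median and 52.6% with the authors' values. The median of all genes was 0.09, and 0.34 and 0.19 under these alternatives. Early response genes (0.44), negative regulators (0.30) with Lag3 at 1.83, MAPK feedback (0.34), serum response factor targets (0.11), Mediator (0.20), cell cycle (0.02), glycolysis (0.46) and ribosome biogenesis (0.54) did not stand apart. The same held for the interferon (-0.06), helper lineage (0.29), regulatory T cell (0.20), apoptosis (0.18), heat shock (0.52), CD8 (0.84), B cell (-0.29), natural killer (-0.44) and stroma (-0.54) lists. Of these, the early response list stood apart in 4 of the 8 alternatives, the stroma list in 2 and the B cell list in 1.

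Between the unstimulated arrays, the B cell, myeloid and dendritic, and effector and memory lists stood above the matched lists in the array labelled knockout. In each list a minority of genes was past the rule. Of 19 B cell genes 8 were 2-fold higher and 0 lower (median 0.94), among them Jchain (9.69-fold, 3.28), the signalling adaptor Blnk (1.88) and the MHC class II chains H2-Eb1 (1.79) and H2-Aa (1.74). Of 24 myeloid and dendritic genes 6 were higher and 0 lower (median 0.70), with Tyrobp (1.78), Itgax (1.26), the integrin chain of dendritic cells, and Batf3 (1.24). With these markers, effector and memory genes had 3 of 27 members higher and 1 lower (median 0.49), with Ccr2 (2.27), Ccl5 (1.62) and Anxa1 (1.16) against Gzmb (-1.41). Ccr2 and Anxa1 are also genes of myeloid cells, so this shift is not assigned to T cells. The naive and quiescence genes had 1 of 32 lower and 0 higher (median -0.27), with Dapl1 8.06-fold lower (-3.01). Il4, the signature cytokine of type 2 helper cells, was 7.2-fold higher (2.85, with a range of 1.93 to 2.85 over the alternatives).

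Smaller shifts stood apart beside those markers. Cytokines had 4 of 26 genes higher and 1 lower, Ccl1 (-2.06), with a median of 0.31. Helper lineage genes had 2 of 26 higher (median 0.24), Maf (1.10) and Il1r1 (1.07). Interferon response genes had 3 of 32 higher and 1 lower (median 0.20), with Oasl2 at least 4.58, Oas1a at 1.66, Oasl1 at 1.65 and Xaf1 at -1.47. Cell cycle genes had a median of 0.28 over 34 genes, and Mki67 differed by 0.88. Of 24 T cell identity genes 0 were past the rule (median 0.05). This list did not stand apart, and neither did the early response (0.02), ribosome biogenesis (-0.06), negative regulators (0.02), MAPK feedback (0.14), serum response factor targets (-0.09), glycolysis (-0.08), regulatory T cell (0.10), cholesterol (-0.06), apoptosis (0.10), heat shock (-0.06), CD8 (0.03), natural killer (0.33), red cell (0.37) or stroma (0.29) genes. Of these, the natural killer list stood apart in 4 of the 8 alternatives, the stroma and apoptosis lists in 2 each, and the negative regulator, MAPK feedback and regulatory T cell lists in 1 each. Egr2 (-0.73), Klf2 (-0.40), Il2 (0.36), Ifng (-0.17), Cdkn1b (-0.07), Il2ra (-0.06) and Cd69 (0.00) were not past the rule.

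Over all genes, 463 of 14008 were higher and 199 lower in the unstimulated array labelled knockout. The higher share was 69.9%, and 59.5% with the floor at the 20th percentile. Dim genes gave most of these calls: 139 were higher and 52 lower among 7467 genes whose brighter array lay above -1, and 324 were higher and 147 lower among the other 6541. Among the largest differences were Cmtm8 (5.60), Tomm22 (2.60), Pirb (2.11), Phlda3 (2.04), Mzb1 (2.03) and Trpm6 (1.98) on the higher side. Rwdd2a (-8.85), Vmn2r85 (-6.16), Bdh2 (-3.61), Nrn1 (-2.98), Cox4i2 (-2.73), F2rl1 (-2.28) and Gpr27 (-2.28) were on the lower side. Cmtm8 has 1 probe and was bright in this array alone, at a level of 0.99.

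After stimulation, the cytokine and cholesterol lists stood above the matched lists in the array labelled knockout, and the naive and quiescence list stood below. Most cytokines were past the rule, but only a minority of the cholesterol and of the naive genes. Of 32 cytokines 17 were 2-fold higher and 1 lower (median 1.13, matched lists 0.11). Ifng was 6.05-fold higher (2.60), with Il6 (2.37), Ccl4 (2.24), Ccl5 (2.23), Il4 (2.18) and Il2 (1.28). Of these, Il4 (2.85) and Ccl5 (1.62) were already past the rule without stimulation. Of 28 cholesterol and lipid genes 10 were higher and 0 lower (median 0.60, matched lists 0.17), with Cyp51 (1.76), Msmo1 (1.59), Hmgcs1 (1.22) and Sc5d (1.21). Of 32 naive and quiescence genes 8 were lower and 0 higher (median -0.39, matched lists 0.26), with Dapl1 (-3.94), Klf7 (-2.21), Il6ra (-1.83) and Cd7 (-1.71). Klf2 (-1.03) and Cdkn1b (-1.17) were lower by the rule, and stayed so in 7 of the 8 alternatives, with ranges of -1.23 to -0.83 and -1.36 to -0.96.

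The early response, helper lineage and ribosome biogenesis lists also stood above the matched lists, though most of their genes were not past the rule. Early response genes had 4 of 33 members higher and 0 lower (median 0.67, matched lists 0.21), with Cd83 (2.08) and Bhlhe40 (1.75), while Egr2 (0.04), Il2ra (0.14) and Cd69 (0.93) were not past the rule, though Cd69 was in 1 alternative. Helper lineage genes had 6 of 26 higher and 0 lower (median 0.47), with the chemokine receptors Ccr8 (2.31) and Ccr4 (2.11) and with Tbx21 (1.78), a place lost with scaling to the median. Ribosome biogenesis genes had 0 of 32 higher and 1 lower, Npm1 (-1.04), with a median of 0.51 that stood apart in 5 of the 8 alternatives. The T cell identity list had 1 of 24 lower, Fyn (-1.05), and a median of 0.17. MAPK feedback (0.29) with Spred1 at 2.16, negative regulators (0.26) with Nfkbia at 1.69 and Lag3 at 1.45, Mediator (0.28), cell cycle (0.36), glycolysis (0.33), interferon response (0.31), effector and memory (0.03), regulatory T cell (0.42), apoptosis (0.11), heat shock (0.49), CD8 (0.87), natural killer (-0.15), stroma (-0.41) and serum response factor genes did not stand apart. The last had 3 of 30 genes lower and 0 higher, Vcl (-1.96), Zfp36 (-1.11) and Ccn1 (-1.05). Of these, the heat shock list stood apart in 3 of the 8 alternatives, and the serum response factor, regulatory T cell and cell cycle lists in 1 each.

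Other cell types moved in opposite directions in this comparison. B cell genes were higher in 8 of 20 and lower in 1 (median 0.51, and 1.13 in the authors' values), with Blnk (2.76), Jchain (2.48) and H2-Eb1 (1.62). Red cell genes were lower in 9 of 10 and higher in 0 (median -3.62, and -1.37 to -2.85 in 4 alternatives) and myeloid and dendritic genes in 15 of 23, with 1 higher (median -1.67, and -3.34 with the brightest probe). The myeloid list had a median of -0.26 in the authors' values and did not stand apart there. By the naming rule the largest lower values were those of Hba-a2 (-10.87), Mpo (-9.08), Plbd1 (-8.69), Ifitm6 (-8.61), Hp (-8.57), Stfa2 (-8.47), Chil3 (-8.23) and Stfa3 (-7.84). On the higher side were Sbk1 (6.49), Oasl2 (3.51), Nkx2-4 (3.48), Fbxo36 (3.30), Olfr213 (3.29), Acot6 (3.24), Ltk (3.20) and Gtpbp3 (3.16). Sbk1 has 1 probe, with a level of 6.67 in this array and 1.70 or lower in the others. In all, 729 of 14629 genes were higher and 1189 lower. The higher share was 38.0%, against 60% with scaling to the median and 51.8% with the authors' values, and the median of all genes was 0.09, or 0.28 with scaling to the median. The stimulated wildtype array enters this comparison, the wildtype stimulation difference and the difference between them, and none can be made without it.

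A small set of genes differed between genotypes in both states. Across genes above the floor in all arrays, the genotype differences without and with stimulation had a Pearson's r of -0.029. These comparisons share no array. Of 13407 genes measured in both, 89 were 2-fold higher in both, where independent lists of 390 and 642 genes would share 18.7. The 46 lower in both compare with 11.3 for lists of 159 and 956. Opposite directions also exceeded independent lists, with 79 genes higher without and lower with stimulation against 27.8, and 12 the other way against 7.6. Values here are the smaller of both differences. The higher genes included Oasl2 (3.51), Jchain (2.48), Il4 (2.18), Stk3 (2.09), Mzb1 (2.03), Zcchc3 (2.03), Trpm6 (1.98), Smtn (1.97), Blnk (1.88) and Apol7c (1.75). Of these Jchain, Mzb1 and Blnk are genes of B or plasma cells. The lower genes included Rbp7 (at most -4.24), Dapl1 (-3.01), Nrn1 (-2.70), Galnt9 (-2.00), Amigo2 (-1.81), Wnt10a (-1.64), Rab6b (-1.63), Tifab (at most -1.60) and Plaur (-1.57).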

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

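The 8 tests of explanations in this part were chosen only after the results they bear on had been seen. The rule that picks genes and lists moving in opposite directions was fixed before the data were examined.

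Stimulation moved 1 of 24 lists and 15 of 285 named genes in opposite directions in the genotypes, each by at least 2-fold for a gene. The named genes were picked in part for such differences. Over the 12217 genes above the floor in all arrays, 61 were 2-fold higher in wildtype and lower in the arrays labelled knockout, and 8 were the reverse. With 1 array per group these differences were not tested. The myeloid and dendritic list had a median log2 difference of 1.66 in wildtype (1.655) and -0.57 in the arrays labelled knockout (-0.575). Some red cell and granulocyte genes were higher in wildtype and lower in the arrays labelled knockout, where the red cell and granule protein lists as a whole had medians of 0.25 and 0.13. These were Hba-a2 at 10.28 and -1.72, Hba-a1 at 10.05 and -1.34, Mpo at 9.70 and -1.22, Ctsg at 8.87 and -1.38 and Lyz2 at 7.71 and -1.28. The second value of Hba-a2 ran from -1.72 to -0.12 over 7 alternatives and was past the 2-fold rule in 6 of them. The wildtype values of Hba-a1, Mpo and Lyz2 and the other values of Hba-a1, Ctsg and Lyz2 are bounds, with an array at the floor. Some other myeloid genes did the same. Plbd1 was at 6.20 and -4.09, Alox5ap at 5.78 and -1.15, Tyrobp at 4.68 and -2.16, Tgfbi at 4.38 and -2.36, Fcer1g at 4.37 and -1.57, Anxa1 at 3.95 and -1.92 and Pirb at 1.38 and -3.05. The cytokine Il24 was at 1.60 and at most -1.55. Cox4i2, a subunit of cytochrome c oxidase, was at -1.79 and 1.19, and the kinase Sbk1 at -1.53 and 5.40.

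The first pattern is the set of granulocyte and red cell genes high in the stimulated wildtype array alone. Brightness or scaling cannot reorder genes within an array, yet the median rank of the granule protein list lay 55.6 percentile points above its highest median elsewhere (92.0 against 36.4), which argues against both. RNA from blood or marrow cells in that sample is a candidate explanation: in the granule protein list, drawn up after the data had been seen and after 8 of its 26 genes had been looked at, 16 of the other 17 measured genes (94.1%) were at least 2-fold higher there than in each other array, with Hba-a2, Elane and Ctsg at levels of 6.89, 5.58 and 5.05. A clean CD4 selection would remove such cells, but how the cells were selected is not given in the sources used here. Induction that needs Med23 stays open, since the list's stimulation median in the arrays labelled knockout, 0.13, repeats the pattern and 1 array per group cannot separate genotype from sample.

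The second pattern is the higher level of cytokines in the stimulated array labelled knockout, where 23 of 32 were at least 1.5-fold higher (median 1.13). Among them Il4 (2.85) and Ccl5 (1.62) were already higher without stimulation. Dilution of T cell RNA by the other cells in the stimulated wildtype array would raise all T cell transcripts alike. The T cell identity list had a median of 0.17 and the naive and quiescence list -0.39, which argues against dilution as the whole cause. The naive list was already lower without stimulation (-0.27), so part of its value does not bear on dilution. The bounds of this test were set with these medians known. Compression of bright signals on the brighter array would act on other genes too. Over 20 bins of genes by signal the median difference was at most 0.41, which argues against compression as the whole cause. This highest median lay in the brightest bin, so compression as a part of the cause stays open. More antigen-experienced cells before stimulation may contribute, as the effector and memory list had a median of 0.49 between the unstimulated arrays, but its genes Ccr2 and Anxa1 are also myeloid, and genotype and cell make-up coincide in the design and cannot be told apart. An effect of Med23 on cytokine genes stays open too, untested.

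The third pattern is the higher level of some genes of antigen-presenting cells in both arrays labelled knockout. The myeloid and dendritic list, written before the data were examined, did not show it in both. Its median was 0.70 without stimulation, but -1.67 with it, where 15 of 23 genes were lower and 1 higher. The second median carries the first pattern too. In the stimulated wildtype array 13 of 25 genes of this list were at least 2-fold higher than in each other array. The largest falls were those of Lyz2 (at most -7.71), S100a9 (at most -7.70) and S100a8 (at most -6.66). This median therefore cannot decide on the third pattern. The mature dendritic list was drawn up after the data had been seen and after 8 of its 36 genes had been looked at, but of its other 25 measured genes 9 were at least 1.5-fold higher in both comparisons, which share no array, where unrelated lists would share 0.35. Of 10000 random lists of like expression 0 reached 9 (highest 4), and 2 of the 25 went in opposite directions. This argues against noise that is independent between genes, such as spot noise. Genes of 1 cell type can rise and fall together, so these counts cannot exclude a chance difference in cell make-up between the samples. More dendritic and B cells in these samples could account for it, but these 9 genes are 36.0% of the 25, between the bounds set for and against this source; among the list's most abundant genes Il4i1 had levels of 3.97 and 3.08 and Fscn1 of 2.23 and 1.83 in the unstimulated and stimulated arrays labelled knockout, and a clean CD4 selection would remove such cells. An effect of the genotype stays open, untested.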

How the results depend on the processing

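Counts without marker genes of other cell types, and counts of genes above the floor in all 4 arrays, were chosen only after the results were seen. No paired analysis was run. Each group has 1 array, and the results come from no test. With 1 array per group no sample could be left out and checks for outlying samples could not apply. The comparisons that use the stimulated wildtype array cannot be made without it, and the other 2 do not use it. Signal over background limits the calls: between spots of a probe the SD of a log2 difference reached 0.83 near the floor. With no replicates, a value counts as moved when it changed by over 1.5-fold, or by 0.1 for a correlation. Of the list medians under alternatives 936 stayed within that bound, 22 moved and 2 reversed, and of the values of named genes 4205 stayed, 276 moved and 1 reversed. Of 120 list medians 53 stood apart, 38 of them in all 8 alternatives, and 15 others did so in some alternative alone. Of 478 values of named genes past the 2-fold rule 121 were not past it in some alternative. All 8 values of the agreement of the genotype difference stayed. Of the gene counts 77 stayed within 1.5 times and 43 did not, and none of those without marker genes of other cell types moved. The marker lists hold too few genes to move the larger counts that far. This result therefore does not show that RNA of other cells had no part in the counts. Quantile normalization, cyclic loess, the pseudocount and the brightest probe moved no count.

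Counts are given as higher and lower genes. With a 1.5-fold threshold they were 3560 and 3530 for stimulation in wildtype, 3435 and 3362 for stimulation in the arrays labelled knockout, 1148 and 628 between the unstimulated arrays, 2678 and 2355 between the stimulated arrays, and 3293 and 2954 for the difference of the stimulation differences. With a 3-fold threshold they were 959 and 657, 851 and 836, 119 and 64, 225 and 527, and 268 and 745, in the same order. The threshold itself sets these. With the floor at the 60th percentile, fewer genes count as measured. The higher genes were then 1203 for stimulation in wildtype, 147 between the unstimulated arrays, 368 between the stimulated arrays and 621 for the difference of differences. The lower genes were 1259 for stimulation in the arrays labelled knockout, and 54, 496 and 666 for the last 3 comparisons. With the floor at the 20th percentile, 779 were higher and 531 lower between the unstimulated arrays, 1183 were higher between the stimulated arrays and 1828 in the difference of differences. In the authors' values, which hold fewer genes, 1316 were higher for stimulation in wildtype, 204 were higher and 72 lower between the unstimulated arrays, 563 were lower between the stimulated arrays and 746 in the difference of differences. Scaling to the median gave 1335 higher genes between the stimulated arrays and 2293 in the difference of differences. Among genes above the floor in all 4 arrays, 284 were higher and 106 lower between the unstimulated arrays, 739 were lower between the stimulated arrays and 1037 in the difference of differences.

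The correlation of the stimulation differences, 0.665, was 0.552 with the floor at the 20th percentile and 0.514 with the pseudocount. The red cell median for stimulation in wildtype was 1.693 in the authors' values, 2.372 with the floor at the 60th percentile and 2.702 with the pseudocount. Between the stimulated arrays it was -1.371, -2.372 and -2.312, and -2.845 with the floor at the 20th percentile. In the difference of differences it was -0.971, -2.372 and -2.502, and -2.90 with the floor at the 20th percentile. The myeloid and dendritic median was -0.264 in the authors' values and -3.341 with the brightest probe between the stimulated arrays. It was -1.073 and -2.633 in the difference of differences, and 2.779 with the brightest probe for stimulation in wildtype. In the authors' values the B cell median between the stimulated arrays was 1.131 and the stroma median 0.308, with 0.091 for stroma in the difference of differences. With the floor at the 60th percentile the cytokine median for stimulation was 1.291 in wildtype and 2.214 in the arrays labelled knockout, and the stroma median in wildtype was -0.722. In the difference of differences, scaling to the median turned the naive and quiescence median to 0.27 and the T cell identity median to 0.252, and the floor at the 60th percentile turned Oasl2 to 0.509. Quantile normalization moved no list median, and the authors' values were close to a quantile normalization of the log2 raw signals. This argues against normalization between arrays as the cause of the list medians that moved in the authors' values. Those values hold fewer genes, and whether this moved the medians was not tested. The cause of the other changes was not tested either.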

Other observations

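The lists in this part were written after the data had been seen, so their results are descriptive. Lists of protein synthesis and turnover genes had positive medians after stimulation in both genotypes, with fewer genes past the 2-fold rule in wildtype. Of 20 measured aminoacyl-tRNA synthetases, the enzymes that load transfer RNAs, 10 were 2-fold higher in wildtype (median log2 difference 1.02) and 18 in the arrays labelled knockout (median 1.46), and 0 were lower in either. Of 31 proteasome subunits 9 were higher in wildtype (median 0.72) and 19 in the arrays labelled knockout (median 1.04), with 0 lower. Both lists stood above the matched random lists in both genotypes. In neither list did the difference between genotypes stand apart with stimulation (0.42 and 0.41) or without (-0.04 and 0.01).

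The mature dendritic and plasma cell lists stood above the matched lists in the arrays labelled knockout, without and with stimulation, although most plasma cell genes were not past the 2-fold rule. Of 33 mature dendritic genes 13 were higher and 0 lower in the unstimulated array labelled knockout (median 0.85), and 18 of 32 were higher and 1 lower in the stimulated one (median 1.09). After their values were seen, Fscn1 (1.40 and 2.48), Mreg (1.60 and 2.23) and Ccl17 (1.71 and 2.58) were picked as examples. Of 10 plasma cell genes 2 were higher without stimulation (median 0.34), and of 9 genes 3 were higher with it (median 0.80), with Jchain and Mzb1 among them. The GIMAP family of lymphocyte GTPases stood apart in none of the 5 comparisons, with medians of -0.21 and -0.08 for stimulation in wildtype and in the arrays labelled knockout, -0.19 and -0.03 between genotypes without and with stimulation, and 0.24 for the difference of differences.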
